A study of Mus musculus with 8 samples.

How the data were processed

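The samples were 8 one-colour arrays of peritoneal macrophage RNA, 4 from wild-type (wt) and 4 from Card9-/- mice. Per the labels, mice received 1 ml of 3% thioglycolate, the peritoneal fluid was taken 4 days later, red cells were lysed, the cells were seeded, and adherent cells were kept after washing 3 h later. Zymosan was given at 500 mg/kg for 4 h in every sample, and 0.2 µg of RNA was labelled with Cy3 per array. The groups and replicate numbers were read from the labels, before the data were examined, as were the tests, the gene lists, the rule for naming genes and most of the alternatives.

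The deposited scanner files hold intensity values that, per the file headers, Agilent Feature Extraction 10.7.1.1 read from each array and subtracted for background, with spatial and multiplicative detrending and surrogates for dim spots, without scaling between arrays. The authors' series matrix holds log2 values, 1 row per probe (56745), that the values show to be quantile normalized, with a median near 4.48 in every column; how the authors made it beyond the scanner software is not stated. After row 49670 of the matrix, the remaining 7075 rows carried the values of the next probe identifier. There 62.5% of values lay over 1.5 log2 units from those of the scanner files under their own identifier and 0% under the next one. Each column matched best a scanner file of its own genotype (8 of 8) and in 2 of 8 the file of its own replicate, so replicate numbers differ between the sources. Because of this the scanner files were used throughout, and the matrix served only as an alternative, with its 49670 aligned rows, which leave out both Card9 probes.

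Control spots were removed, leaving 59305 spots of 56605 probes per array. The processed signal was taken to log2 and the 75th percentile of the array's non-control spots subtracted. Spots marked by the scanner software as non-uniform or population outliers (63 to 213 per array) were set to missing, a probe needing 3 usable arrays in each group, and repeated spots of a probe were averaged. Probes were kept where well above background on at least 3 of 4 arrays of either group (28166 probes), and the probe with the highest mean over all 8 arrays stood for each gene, which gave 18603 genes. Gene names came from the accession in the files (32994 probes), from a current symbol (10224) or a unique synonym (520) in the GRCm38.p6 gene table, and otherwise stayed as in the files (12867). Coordinates are those in the files, on mm9.

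The share of spots well above background was 55.3, 56.5, 52.9 and 51.8% in wt replicates 1 to 4 and 47.8, 52.4, 48.2 and 51.8% in Card9-/- replicates 1 to 4, and the 75th percentile of the signal was 352, 482, 380 and 893, and 219, 531, 242 and 195. The median of the spot coefficient of variation was 2.85% to 6.51% per array. The arrays of wt replicates 1 and 2 lay closest together (correlation 0.985) over the genes tested, with 1 probe per gene. Both correlated better with Card9-/- replicates 2 and 3 (0.920 to 0.963) than with wt replicates 3 and 4 (0.822 to 0.895). Over 21296 probes bright on all arrays the SD of their difference was 0.398, against 1.11 to 1.71 for the other pairs of wt arrays and 0.630 for Card9-/- replicates 2 and 3. Repeated spots within arrays would give 0.0830 (287 probes), without the noise of labelling and hybridization, so whether both arrays hold the same RNA stays open. They were kept as the 2 samples that the labels give, and averaging them was an alternative.

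Genotypes were compared with limma 3.58.1 in R 4.3.3 (data.table package, version 1.17.8), with an intercept and genotype, empirical Bayes moderation with a constant prior, two-sided tests and Benjamini-Hochberg adjustment over all genes at 0.05, also counted at 2-fold or more. For genes not well above background on any array of one group, the fold is given as a bound, which holds only for the scanner software's background subtraction. Gene and marker lists (39 with at least 5 measured members) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 39 lists. Beside it stand the number of members past the threshold over all genes and over the list alone, and the exact two-sided permutation p of the list mean over all 70 assignments of 4 of 8 arrays. Camera with an estimated correlation and fry were alternatives.

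Card9 was named first. Of genes past the threshold that were above background in each group, up to 12 per direction were to be named, then up to 4 per direction seen in 1 group alone, filled to 12 by the smallest unadjusted p and said not to pass. Of each list described, up to 4 members past the threshold, or else the 1 with the smallest p, were named. Genes known only by accession or clone name were counted and not named, and the leading gene of 2 lists is not reported here. Of the lists not called, 10 on autophagy, Card9 and the response to zymosan are described, a choice not fixed beforehand, and the other 17 are given as a count and a range.

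The pipeline was tested on simulated data: over 10 simulations of 18603 genes with 500 changed genes per fold, it recovered 0.8% of 2-fold, 26.2% of 4-fold, 75.8% of 16-fold and 97.2% of 256-fold changes, and 4.58% of its calls were false. A shift of 1 log2 unit added to the T cell list was called in 10 of 10, and other lists in 2 of 380 tests. Noise was drawn independently for each gene, so these list calls leave out the correlation between genes of a list. In the real data it was estimated at 0.22 for the T cell list and 0.60 for the natural killer list. The simulation therefore does not show how often real lists are called falsely.

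Alternatives were quantile normalization, median scaling, normexp background correction (offset 50), the authors' matrix, 2 other filters on dim probes, the mean of a gene's probes, every probe separately, outlier spots kept, trend and robust moderation, array weights, blocks for replicate number, slide and scan date, and each array left out in turn. Chosen after seeing the data were slide 1 alone, the slide as a random block, genes on X or Y left out, wt replicates 1 and 2 averaged, and wt replicates 1 and 2 or 3 and 4 set aside. All 35 splits of the 8 arrays into 4 and 4 were run through the same tests. Tables were read with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.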

Results

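Gene expression was measured in peritoneal macrophages of wild-type mice (wt) and of mice lacking Card9 (Card9-/-) with 8 one-colour Agilent arrays, 4 per genotype. Card9 is the adaptor through which C-type lectin receptors such as Dectin-1, a receptor for the beta-glucan of yeast walls, signal to NF-kB together with Bcl10 and Malt1. Every mouse had received zymosan, a yeast cell wall preparation that causes peritonitis, at 500 mg/kg for 4 h. Untreated mice were not analysed here, so each value compares the genotypes after zymosan. The labels do not say whether an array holds the RNA of 1 mouse or of a pool, and p-values therefore measure only the spread between these samples. Between 28326 and 33503 of the 59305 non-control spots of an array (47.8% to 56.5%) were well above background, and 0 spots were saturated. Levels are log2 processed signals relative to the array's own 75th percentile, so that a level of 0 is that percentile. The number of arrays limits the precision. All 4 wt arrays and Card9-/- replicate 4 shared slide 1 and a scan. Card9-/- replicates 1 and 3 shared slide 2 and were scanned on different days, and Card9-/- replicate 2 was on slide 3.

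The deleted gene was examined first, because its level checks the genotype labels. Card9 RNA was not well above background on any Card9-/- array, while 3 of the 4 wt arrays carried it at very different levels. At the brighter of the 2 Card9 probes (chromosome 2, 26208066 to 26208504, mm9, starting at base 1390 of the transcript), the processed signal was 1058 in wt replicate 3, 561 in wt replicate 4 and 38.2 in wt replicate 2. The library labelled wt replicate 1 gave a signal of 4.75, not well above background, and the Card9-/- libraries gave 3.60, 11.9, 8.85 and 4.52. These signals are not scaled between arrays. The lowest level well above background was -4.84 to -4.31 on wt arrays and -4.17 to -3.47 on Card9-/- arrays. The level of wt replicate 2 (-3.66) lay below that limit on Card9-/- replicates 1 (-3.64) and 4 (-3.47). The mean level was -2.27 ± 3.37 (SD, n = 4) in wt and -5.40 ± 0.48 (SD, n = 4) in Card9-/-, so that Card9-/- was at least 2.78-fold lower, a bound that fell to 1.17-fold without wt replicate 3 and rose to 6.92-fold without the library labelled wt replicate 1. With normexp background correction the fold was 2.30. The difference of -3.14 (SE 1.39) had an unadjusted limma p of 0.0494, and 0.689 after adjustment over all genes tested. By the exact two-sided permutation test it did not exceed the spread between the arrays (p = 0.143 over 70 permutations). The difference ranged from -4.45 without the library labelled wt replicate 1 to -1.89 without wt replicate 3. The other probe (26212384 to 26212744, starting at base 911) was well above background on 2 wt arrays and 0 Card9-/- arrays, with a difference of -1.55 (exact permutation p = 0.171) and no bound above 1. Which part of Card9 is deleted is not given in the sources used here, so a probe outside that part would check nothing.

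Across the genome, the genes that passed the threshold were those of the sex chromosomes. The Card9-/- libraries carried the Y-linked transcripts Eif2s3y, Ddx3y and Uty, which encode a translation initiation factor subunit, an RNA helicase and a protein of the histone demethylase family, and the wt libraries did not. The wt libraries instead carried Xist, the RNA that coats the inactive X chromosome of female cells. Eif2s3y (chromosome Y, 364900 to 364959, mm9) was at least 50.1-fold higher in Card9-/- (log2 difference 7.82, SE 0.49, adjusted p = 0.000382). Ddx3y (599275 to 599334) was at least 15.7-fold higher (6.17, SE 0.39, adjusted p = 0.000382) and Uty (471281 to 471340) at least 43.5-fold (7.16, SE 0.57, adjusted p = 0.0013). An unnamed transcript beside them (chromosome Y, 357543 to 357602), chosen after its values were seen, was at least 56.3-fold higher. Its probe lies close to that of Eif2s3y and may read the same RNA, although the 2 were counted as 2 genes. Each of these 4 Y-linked probes was well above background on 4 of 4 Card9-/- arrays and 0 of 4 wt arrays. A probe that the files name XIST (chromosome X, 100655839 to 100655898) was at least 210-fold lower in Card9-/- (log2 difference -8.99, SE 0.64, adjusted p = 0.000631). A probe named Xist (100662174 to 100662233) was at least 22.4-fold lower without passing the threshold (-6.43, SE 0.80, adjusted p = 0.054). Its bound was 15.5-fold without wt replicate 2 and 35.8-fold without wt replicate 3. The 2 names were counted as 2 genes, although these probes lie close together and may read 1 RNA. Both were well above background on 4 of 4 wt arrays and 0 of 4 Card9-/- arrays. These bounds hold for the scanner software's background subtraction alone. With normexp the folds were smaller, at 17.0 for Eif2s3y, 6.58 for Ddx3y, 15.4 for Uty, 19.3 for the unnamed transcript and 70.1 for XIST, all still past the threshold (adjusted p of 0.00304 to 0.0335), and 9.31 for Xist. Of the other 6 Y-linked genes tested, none passed or separated the genotypes, Kdm5d among them (-0.67, adjusted p = 0.854). Each of the 6 was well above background on 3 or 4 wt arrays, where the 4 Y-linked probes above were not. The probes of the 6 thus gave signal where those 4 did not, and do not tell whether Y-linked RNA was present.

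In all, 5 of the 18603 genes tested passed an adjusted p of 0.05 (limma), 4 higher and 1 lower in Card9-/-, each by over 2-fold. Of the 5, 0 lay on an autosome. At an unadjusted p under 0.05 there were 1344 genes, 490 higher and 854 lower. All 4 arrays of one genotype lay on one side of the other 4 for 971 genes (5.22%), against 2.86% by chance. Of the 34 other splits of the arrays into 4 and 4, 7 gave more such genes, up to 1979, so this count does not mark genotype. With the authors' processed values the split was 4 higher and 2 lower. Without the library labelled wt replicate 1, whose Card9 signal was not above background, it was 4 higher and 1 lower. Without wt replicate 3, the probe named Xist passed beside the one named XIST (-7.11, adjusted p = 0.0106). This made 2 lower by name, which may be 1 transcript. With the slide as a block, where the contrast rests on Card9-/- replicate 4 alone, 0 genes passed in limma (1660 at an unadjusted p under 0.05) and Eif2s3y still differed by 6.58 (adjusted p = 0.0801). Within slide 1, 234 genes passed, 233 of them higher in that 1 Card9-/- array. Sex, as these transcripts mark it, cannot be told apart from genotype in any comparison. Each Card9-/- library carried Y-linked transcripts and each wt library carried Xist.

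**Figure D1:**
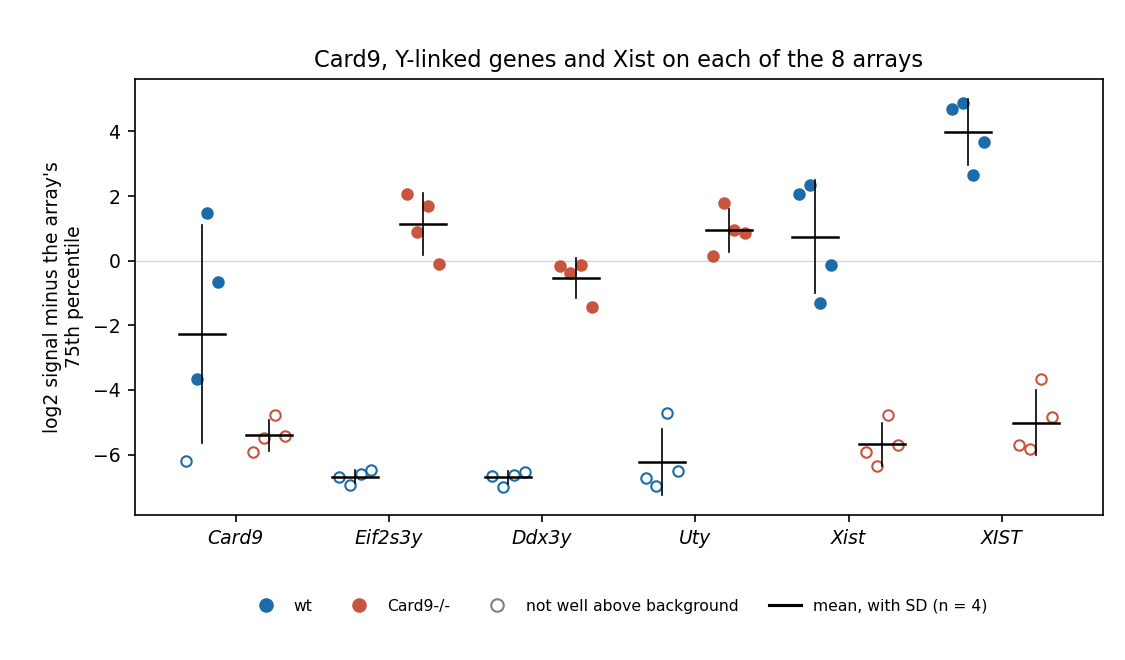
Level of Card9 and of sex-linked transcripts on each array (log2 signal relative to the array's 75th percentile; points are single arrays, open where not well above background; bars are group means with SD, n = 4 per genotype). The Y-linked transcripts and Xist part the genotypes completely, while Card9 runs in wt from -6.21 in the library labelled wt replicate 1 to 1.48 in wt replicate 3.

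Outside the sex chromosomes, the genes with the smallest p-values that were higher in Card9-/- included several of cytotoxic lymphocytes, and none of them passed the threshold. Cd8a, the co-receptor of cytotoxic T cells (chromosome 6, 71328911 to 71328970), was higher by 3.22 log2 units (SE 0.52, adjusted p = 0.231), and Klrb1c, the NK1.1 receptor (chromosome 6, 128728603 to 128728662), by 3.20 (SE 0.59, adjusted p = 0.301). The differences were smaller for Cd96, a receptor of T and natural killer cells (2.68, adjusted p = 0.301), and for Ctsw, a protease of the same cells (2.27, adjusted p = 0.312). The remaining differences on this side were 3.06 for Tff3, a trefoil peptide of mucosal secretions, 2.80 for Lzts1, 2.69 for the lipocalin Lcn4, which lies near Card9 (chromosome 2, 26523247 to 26523306), 2.55 for Dapl1 and 2.22 for the sorting nexin Snx29, with adjusted p between 0.255 and 0.288. Tff3 was well above background on only 1 wt array, and Cd8a, Lcn4 and Dapl1 on 2, so their wt values lie mostly at background. With normexp their differences were 1.47, 1.83, 1.51 and 1.46. On the lower side, none of these passing either, Ucp1, the uncoupling protein of brown fat, had the largest difference (-5.38, SE 0.86, adjusted p = 0.223). It was at least 11.7-fold lower, being well above background on 4 wt arrays and 0 Card9-/- arrays, and the bound was 6.54-fold without wt replicate 3 and 18.1-fold without the library labelled wt replicate 1; with normexp the fold was 4.66. Of genes likewise above background on 0 Card9-/- arrays, Fsd1l was at least 1.31-fold lower (adjusted p = 0.142) and the steroid dehydrogenase family gene Hsd17b13 at least 1.13-fold (adjusted p = 0.451), the latter with no bound above 1 without wt replicate 3. With normexp these 2 folds fell below their bounds, to 1.05 and 1.06. Tcp10b (adjusted p = 0.441) and Cdh15 (adjusted p = 0.514) had no bound above 1, and with normexp background correction their differences turned positive (0.14 and 0.014). Fblim1, a filamin-binding protein, differed by -3.42, Coprs by -1.84, the ribosomal protein-like gene Rps27l by -1.76, the actin regulator Cttn by -1.74 and the X-linked Renbp by -1.52, with adjusted p of 0.451 to 0.514. Coprs was well above background on only 1 Card9-/- array and Fblim1 on 2, and with normexp they differed by -0.53 and -1.81. In Fsd1l, Rps27l, Cttn and Cdh15, 1 library stood apart from the other 3 of its genotype.

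Markers of T cells and natural killer cells were higher in the Card9-/- libraries as whole groups. Of the T cell list, fixed before the data were examined, all 19 measured genes were higher. Its mean level was 2.13 ± 0.38 (SD, n = 4) in Card9-/- against 0.80 ± 0.31 (SD, n = 4) in wt, a shift of 1.33. Of the natural killer cell list all 13 measured genes were higher, with means of 1.49 ± 1.12 and -0.68 ± 0.35 (SD, n = 4 each), a shift of 2.17. The per-array means of the natural killer list were -0.98, -0.18, -0.82 and -0.76 in wt replicates 1 to 4 and 2.93, 1.56, 0.22 and 1.22 in Card9-/- replicates 1 to 4. Besides Cd8a and Klrb1c, and chosen after their values were seen, Cd8b1 (2.18, SE 0.53), the T cell receptor kinase Zap70 (1.73, SE 0.44) and the receptor chain Cd3d (1.71, SE 0.45) were among the T cell genes. Of the natural killer genes, chosen likewise, Nkg7 (2.27, SE 0.52), Klrd1 (2.40, SE 0.57) and granzyme B, Gzmb (2.98, SE 0.78), led. Adjusted over the list alone, 15 T cell genes and 12 natural killer genes passed. Adjusted over all genes tested, 0 of either did, with 15 and 12 at an unadjusted p under 0.05 (limma). Both lists were called by camera with a preset correlation (adjusted p = 5.36e-17 and 8.15e-17), and neither with an estimated correlation (adjusted p = 0.193 for T cells and 0.364 for natural killer cells). The exact permutation p of each was 0.0286, the smallest that 70 permutations can give, and 0.371 after adjustment over 39 lists. The shifts were 1.24 and 1.91 with the slide as a block and within slide 1, which both rest on Card9-/- replicate 4. They were 1.35 and 2.07 without the library labelled wt replicate 1, and at least 1.08 and 1.83 with median scaling, quantile normalization or normexp.

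**Figure D2:**
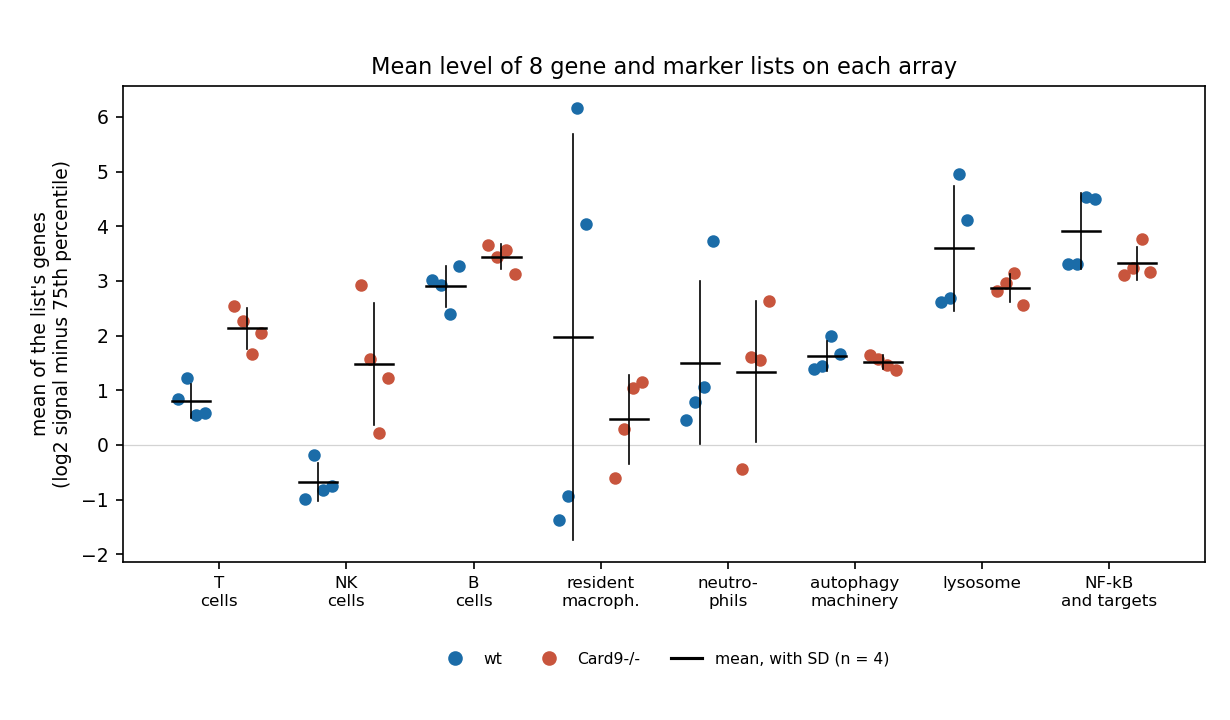
Mean level of the members of 8 gene and marker lists on each array (log2 signal relative to the array's 75th percentile; points are single arrays, bars are group means with SD, n = 4 per genotype). T cell and natural killer lists lie higher on all 4 Card9-/- arrays than on any wt array, while the resident macrophage list runs from -1.36 to 6.16 within wt.

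In all, camera called 12 of the 39 lists with a preset correlation, 5 higher and 7 lower in Card9-/-, and limma's estimated correlation left 0 (2 lists at an unadjusted p under 0.05), as did fry. The median of all genes lay at -0.088, and it moved by -0.18 with median scaling and by 0.12 with normexp, against which list shifts of that size have to be read. Without Card9-/- replicate 4 camera called 7 lists, and without wt replicate 2 it called 21.

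Of the other cell types, B cell markers had a mean shift of 0.55, with 14 of 17 measured genes higher (preset adjusted p = 0.000495; adjusted p = 0.821 with an estimated correlation). Red cell and platelet markers shifted by 1.35 with 11 of 12 higher (0.00199; adjusted p = 0.973 with an estimated correlation). Dendritic cell markers shifted by 0.47 with 8 of 13 higher (0.0238; adjusted p = 0.973 with an estimated correlation). No member of the 3 lists passed, either adjusted over the list alone or over all genes (0 in limma; 2 B cell, 1 red cell and 2 dendritic genes at an unadjusted p under 0.05). Leading genes were the B cell complement receptor Cr2 (1.15, SE 0.41, adjusted p = 0.593) and, of the dendritic list, the integrin Itgae (1.18, SE 0.39, adjusted p = 0.570). With the slide as a block, as within slide 1, the B cell shift was 0.22 (blocked adjusted p = 0.643) and the dendritic shift 0.52 (0.356), no longer called, and the red cell shift 3.79 (3.86 within slide 1). The red cell call was lost without wt replicate 4 (0.76, adjusted p = 0.0851) or Card9-/- replicate 4 (0.54, adjusted p = 0.337), and with array weights (0.70, adjusted p = 0.1502). The dendritic call was lost without the library labelled wt replicate 1 (0.20), wt replicate 2 (0.25), or Card9-/- replicate 1 (0.21), 2 (0.41) or 4 (0.22), with adjusted p of 0.0599 to 0.215. Without wt replicate 3 or 4 its shift was 0.72 or 0.71. It was also lost with normexp (0.22, adjusted p = 0.121), with the mean of a gene's probes (0.36, 0.0569), in the series matrix (0.46, 0.0961) and with wt replicates 1 and 2 averaged (0.23, 0.125). Without a filter on dim probes none of the 3 lists was called (B cells 0.55, adjusted p = 0.313; red cells 1.24, 0.350; dendritic cells 0.25, 0.679).

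Lists that were lower in Card9-/- covered the lysosome, mitochondrial respiration, ribosomal proteins, stress responses, NF-kB targets and the resident macrophage. Of 45 measured lysosomal genes 43 were lower, with a mean shift of -0.72 (preset adjusted p = 1.87e-05), led by the cathepsin gene Ctsz (-0.77, SE 0.38, adjusted p = 0.726). Its mean stood at 2.62 in the library labelled wt replicate 1, 2.69 in wt replicate 2, 4.96 in wt replicate 3 and 4.11 in wt replicate 4, and at 2.56 to 3.15 in Card9-/-. The shift thus came from wt replicates 3 and 4, which were also the highest in the resident macrophage list. The same 2 libraries stood out in the NF-kB list (3.30, 3.31, 4.54 and 4.50 in wt, 3.12 to 3.77 in Card9-/-) and in the endoplasmic reticulum stress list (2.58, 2.83, 4.08 and 3.44 in wt, 2.22 to 3.12 in Card9-/-). All 39 oxidative phosphorylation genes were lower (-0.42; 0.000326), led by the ATP synthase subunit gene Atp5j (-0.82, SE 0.36). Of 44 ribosomal protein genes 43 were lower (-0.50; 1.1e-06), led by Rpl37 (-1.33, SE 0.45), which was well above background on 1 Card9-/- array and turned to 0.22 with normexp. All 14 heat shock genes were lower (-0.67; 0.00409), led by the chaperone Hspa8 (-1.21, SE 0.45). Of 27 endoplasmic reticulum stress genes 25 were lower (-0.51; 0.00828), led by Sel1l (-1.16, SE 0.33), and of 27 NF-kB family and target genes 23 (-0.59; 0.00199), led by the caspase-8 regulator Cflar (-1.01, SE 0.36). None of these leading genes passed (adjusted p of 0.534 to 0.726), and 0 members of the 6 lists did so adjusted over the list alone or over all genes (limma; 12 lower at an unadjusted p under 0.05). With an estimated correlation the adjusted p was 0.821 for heat shock and 0.973 for the other 5; the exact permutation p of heat shock was 0.0286, and 0.371 after adjustment over 39 lists.

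The lysosomal list was called with median scaling, normexp and quantile normalization, the last of which ended the calls of the other 5 (shifts of -0.33 to -0.067, adjusted p of 0.252 to 0.763). In the series matrix the same 5 calls were lost (-0.48 to -0.14, adjusted p of 0.139 to 0.547). With array weights the lysosomal list was called in the opposite direction (0.22, adjusted p = 0.0397), NF-kB (0.031, 0.768) and endoplasmic reticulum stress (0.057, 0.676) turned, and oxidative phosphorylation lost its call (-0.12, 0.419), while heat shock (-0.52, 0.0112) and ribosomal proteins (-0.53, 3.19e-07) kept theirs. Without wt replicate 3 the lysosomal shift was -0.28 (adjusted p = 0.103), oxidative phosphorylation -0.19 (0.162), endoplasmic reticulum stress -0.23 (0.249) and NF-kB -0.38 (0.0253). Without Card9-/- replicate 4 the calls of heat shock (-0.55, adjusted p = 0.110), endoplasmic reticulum stress (-0.35, 0.374) and NF-kB (-0.54, 0.0924) were lost. With the slide as a block the shifts were -1.04 for the lysosome, -0.60 for oxidative phosphorylation, -1.03 for heat shock, -1.01 for endoplasmic reticulum stress and -0.74 for NF-kB, and -0.34 for ribosomal proteins (adjusted p = 0.0537; -0.27 within slide 1, 0.0448). The other 5 were equal within slide 1 after rounding, and both contrasts rest on Card9-/- replicate 4 alone.

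Genes of large resident peritoneal macrophages differed far more within the wt group than between the genotypes. The mean of the list was -1.36 in the library labelled wt replicate 1, -0.93 in wt replicate 2, 6.16 in wt replicate 3 and 4.04 in wt replicate 4, and it was -0.60, 0.29, 1.04 and 1.15 in Card9-/- replicates 1 to 4. Adgre1, which encodes F4/80, stood at 0.67, 0.35, 7.72 and 5.92 in wt and at 1.62 to 2.42 in Card9-/-. Csf1r, the receptor for macrophage colony-stimulating factor, stood at 1.32, 1.02, 8.58 and 5.34 in wt and 2.24 to 3.73 in Card9-/-. Both were chosen after their values were seen. All 19 measured members had a lower mean in Card9-/- (shift -1.51, preset adjusted p = 0.0299; adjusted p = 0.973 with an estimated correlation; exact permutation p = 0.457), led by the acute-phase gene Saa3 (-2.31, SE 1.46, adjusted p = 0.801). The shift was -2.73 without the library labelled wt replicate 1, -2.57 without wt replicate 2, -0.051 without wt replicate 3 and -0.76 without wt replicate 4. Without Card9-/- replicate 1, 2 or 4 it was -1.15, -1.45 and -1.74. The call was lost in the last 5 of these 7 (adjusted p of 0.107 to 0.755). It was also lost with median scaling (adjusted p = 0.0627) and with the slide as a block or within slide 1 (-0.82; 0.643 and 0.320), in the series matrix (-1.26, 0.0921) and with signal required on all 8 arrays (-1.34, 0.127). With array weights the list turned and was called higher in Card9-/- (1.25, adjusted p = 0.00203).

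**Figure D3:**
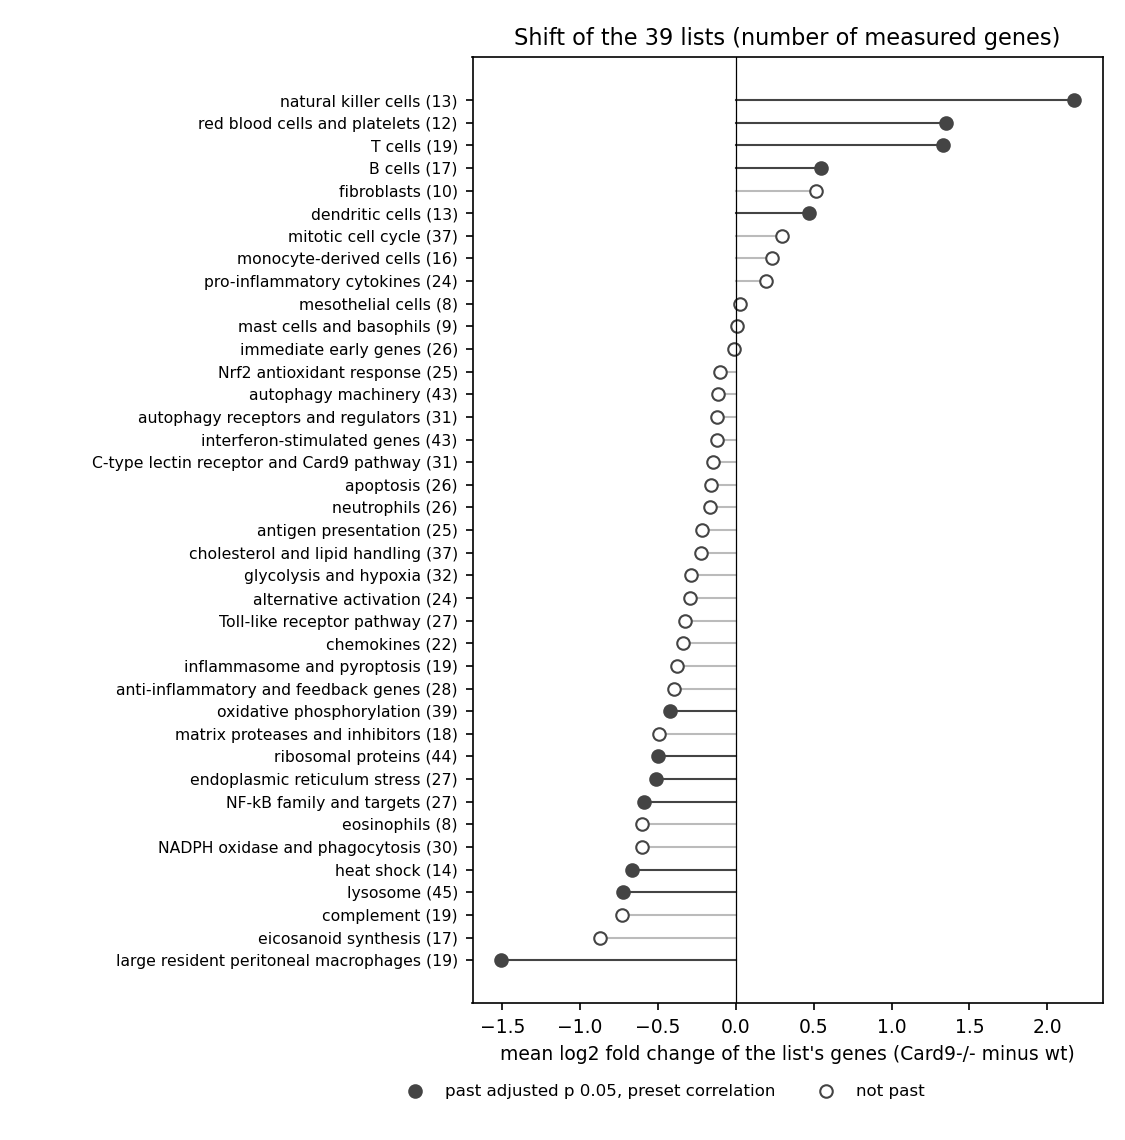
Mean log2 fold change of the genes of each of the 39 lists (Card9-/- minus wt; 1 point per list, filled where past an adjusted p of 0.05 with a preset correlation and open otherwise; measured genes in brackets). The autophagy lists lie at -0.11 and -0.12, and the T cell and natural killer lists at 1.33 and 2.17.

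The title of the series concerns autophagy in macrophages, and neither autophagy list was called between the genotypes in the main design. Of the 43 genes of the autophagy machinery, all measured, 15 were higher and 28 lower in Card9-/-, with a mean level of 1.52 ± 0.12 against 1.63 ± 0.27 (SD, n = 4 each) and a shift of -0.11 (preset adjusted p = 0.820; exact permutation p = 0.514). Of 31 measured receptors and regulators of autophagy 15 were higher and 16 lower, with a shift of -0.12 (preset adjusted p = 0.903). No member of either list passed, adjusted over the list alone or over all genes (0 in limma; 2 and 1 at an unadjusted p under 0.05, all lower). The smallest p-value of the machinery belonged to Atg13, a subunit of the kinase complex that starts autophagy (-1.40, SE 0.44, adjusted p = 0.554). Of genes chosen after their values were seen, Uvrag differed by -0.88 (SE 0.33), the cargo receptor Sqstm1 by -0.69 (SE 0.31) and Becn1 by 0.29 (SE 0.32). The difference was 0.36 (SE 0.41) for Rubcn, which encodes the autophagy inhibitor Rubicon, and 0.29 (SE 0.53) for Map1lc3b, which encodes LC3B (-0.20 without Card9-/- replicate 4), and adjusted p ran from 0.612 to 0.943. The shift of the machinery list was 0.020 with quantile normalization, 0.013 without wt replicate 3, and -0.19 and -0.17 without the library labelled wt replicate 1 and wt replicate 2. With the slide as a block and within slide 1 it was -0.26, and that of the receptors was 0.017 and 0.14. Without a filter on dim probes both lists were called lower, with shifts of -0.11 each (adjusted p = 0.000758 for the machinery and 0.00894 for the receptors). In simulated data of this size, 0.8% of genes changed by 2-fold and 26.2% of those changed by 4-fold were recovered. Those genes were drawn at random from all genes tested, and autophagy genes were not simulated apart. Changes of single autophagy genes of that size may therefore have been missed, at a rate not measured here.

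Beside the NF-kB list, which was called lower with the preset correlation but not with an estimated one or fry, 5 lists of inflammatory signalling and neutrophils were not called. The C-type lectin receptor and Card9 pathway shifted by -0.15 (31 genes, 20 lower, adjusted p = 0.903), with Card9 as its leading gene, and chemokines by -0.34 (22 genes, 15 lower, adjusted p = 0.903), led by Ccl17 (1.48, SE 0.75, adjusted p = 0.736). Pro-inflammatory cytokines shifted by 0.20 (24 genes, 14 higher, adjusted p = 0.263), led by interferon beta, Ifnb1, which was higher in all 4 Card9-/- libraries than in any wt library without passing (2.89, SE 0.83, adjusted p = 0.534). Interferon-stimulated genes shifted by -0.12 (43 genes, 23 lower, adjusted p = 0.903), led by Oas2 (-0.78, SE 0.47, adjusted p = 0.787), and neutrophil markers by -0.17 (26 genes, 15 lower, adjusted p = 0.903), led by Ly6g (-1.14, SE 0.64, adjusted p = 0.767). For the C-type lectin, chemokine and neutrophil lists camera's own direction was up although mean and median were negative. Of the members of the 5 lists, 0 passed adjusted over the list alone or over all genes (limma; 2 cytokines and Card9 at an unadjusted p under 0.05).

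These shifts hung on single libraries and on the weight given to each. Without wt replicate 4, whose interferon-stimulated genes stood at 5.21 against 2.21 to 2.45 in the other wt libraries, the interferon-stimulated list turned to 0.59 (adjusted p = 4.29e-08) and chemokines to 0.38 (0.0237). Neutrophils turned to 0.57 (0.00241) and the C-type lectin list to 0.22 (0.245), and cytokines stood at 0.80 (0.000171). Without wt replicate 3, chemokines stood at 0.33 and the C-type lectin list at 0.18; without Card9-/- replicate 1, neutrophils stood at 0.43 (0.0145). Without the library labelled wt replicate 1 or wt replicate 2, cytokines stood at -0.30 and -0.13. Without a filter on dim probes, chemokines (-0.35, adjusted p = 0.0204), neutrophils (-0.22, 0.0162), the C-type lectin list (-0.13, 0.0161) and interferon-stimulated genes (-0.14, 0.00205) were called lower. Array weights, which rest the wt mean mostly on wt replicates 1 and 2, instead called all 5 lists higher: cytokines by 1.09 (adjusted p = 0.000129), chemokines by 0.99 (0.000371), the C-type lectin list by 0.56 (0.0106), neutrophils by 0.54 (0.0249) and interferon-stimulated genes by 0.48 (0.00203). Quantile normalization turned the C-type lectin list to 0.012 and the interferon-stimulated list to 0.10. With the slide as a block the shifts were -0.31 for the C-type lectin list, 0.33 for cytokines, -0.041 for chemokines, -0.27 for interferon-stimulated genes and 1.12 for neutrophils (adjusted p = 0.00485), and within slide 1 they were equal except for neutrophils at 1.07 (0.114).

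Lists of the recognition and uptake of zymosan were not called either, and they followed wt replicates 3 and 4. The Toll-like receptor pathway shifted by -0.33 (27 genes, 19 lower, adjusted p = 0.263), led by the integrin Itgam (-1.32, SE 0.67, adjusted p = 0.738). NADPH oxidase and phagocytosis shifted by -0.61 (30 genes, 25 lower, adjusted p = 0.277), led by the receptor kinase Tyro3 (0.96, SE 0.33, adjusted p = 0.574), and complement by -0.73 (19 genes, 15 lower, adjusted p = 0.523), led by Serping1 (1.61, SE 1.01, adjusted p = 0.795). With an estimated correlation the adjusted p of each was 0.973. No member passed, adjusted over the list alone or over all genes (0 in limma; Tyro3 at an unadjusted p under 0.05). The mean of the phagocytosis list was -0.35, -0.082, 4.17 and 2.98 in wt and 0.85 to 1.33 in Card9-/-. Without the library labelled wt replicate 1 the phagocytosis (-1.32, adjusted p = 0.000882) and complement lists (-1.64, 0.00256) were called lower, and without wt replicate 2 all 3 were (-1.23, 0.000877; -1.41, 0.0257; Toll-like receptors -0.57, 0.0257), as with wt replicates 1 and 2 averaged. Without wt replicate 3 the phagocytosis and complement lists turned to 0.22 and 0.27, and the Toll-like receptor shift was -0.067. Without a filter on dim probes all 3 were called lower (adjusted p of 0.000221 to 0.00624). Phagocytosis was called lower with normexp (-0.70, 0.0183) and, like the Toll-like receptors, with every probe separately. With array weights all 3 turned, phagocytosis (1.07, adjusted p = 1.59e-05) and complement (1.24, 0.000204) being called higher and Toll-like receptors not (0.29, 0.242). The other 17 lists of the 39 were not called, with adjusted p of 0.0539 to 0.903.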

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

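Of the tests in this part, the splits of the arrays and the other scalings were planned; the tests of sex, swapped libraries, macrophage share, slide and wt labels, and the use of the scalings as a test, were chosen only after the result was seen.

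In 9 of 168 groups of 4 arrays, 1 array lay so far from the other 3 that its gap to the nearest passed Dixon's critical value for 4 samples; chance alone marks about 1 in 20 groups. They were the level of Cdh15 in wt replicate 3 (-5.15), the mean of the interferon-stimulated list in wt replicate 4 (5.21), and the levels of Fsd1l (-5.02) and Rps27l (3.75) in Card9-/- replicate 2 and of Cttn (-3.78) in Card9-/- replicate 1. The others were the antigen presentation (4.15) and apoptosis (1.46) list means in Card9-/- replicate 4, the cholesterol and lipid handling list mean in Card9-/- replicate 3 (1.39), and the 75th percentile of the signal in Card9-/- replicate 2 (531).

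All 5 genes past the threshold lay on the X or Y chromosome. A swap of libraries between the genotypes stays open, since the sex-linked transcripts were found by the comparison itself and mark sex, not genotype. Both Xist and the Y-linked transcripts that passed were seen together on 0 arrays. Of the other 6 Y-linked genes, 0 parted the genotypes. Those 6 cannot test a swap, since each was well above background on 3 or 4 wt arrays, where the transcripts that passed were not. Card9 ran as the labels say, well above background in wt replicates 2, 3 and 4 (signals of 38.2, 1058 and 561) and on 0 Card9-/- arrays. But its absence from the library labelled wt replicate 1 shows that a lack of signal does not prove the genotype. A difference in the sex of the mice fits, with 0 called genes outside X and Y, and it would make every genotype comparison here a comparison of sexes too. Of 35 splits of the arrays 2 gave as many genes, the real one with 5 and another with 43, and 25 gave as many lists as the real 12, the highest other split 31, so chance is not excluded for either count; at an unadjusted p under 0.05, 9 of the 34 other splits gave more genes than the real 1344, up to 3591 where wt replicates 1 and 2 stood against 3 and 4, which points to a structure of the samples beside genotype. Whether the wt mice were female and the Card9-/- mice male stays untested beyond these transcripts.

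T cell and natural killer markers were higher in the Card9-/- libraries, and among the 35 splits the real one had the largest shift of both lists. That rank restates the exact permutation p of 0.0286 given above, which was 0.371 after adjustment over 39 lists. The scaling of the arrays is argued against, since the smallest T cell shift under 3 other scalings was 1.08. A lower share of macrophages stays open: the 2 wt libraries below every Card9-/- library in the resident macrophage list were also lower in the T cell (by 1.098, SE 0.31) and natural killer lists (by 2.07, SE 0.87), but likewise in dendritic (by 1.201, SE 0.31), fibroblast (by 1.85, SE 0.55) and B cell markers (by 0.48, SE 0.18), and they may hold the same RNA. The slide stays open too, since only Card9-/- replicate 4 shared the wt slide; its natural killer mean lay 1.41 above the highest wt array, and 1 library decides nothing. The values may reflect more T and natural killer cells among the adherent cells, and genotype, sex and the handling of the mice all remain open as reasons.

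Macrophage genes spread widely among the wt libraries. The slide or scan is argued against, since the resident macrophage list ranged over 7.53 log2 units among 4 wt arrays of 1 slide and scan. Card9-/- RNA under a wt label stays open: 0 wt libraries carried the Y-linked transcripts that marked every Card9-/- library, but those were picked for parting the labels, and wt replicates 1 and 2 correlated better with Card9-/- replicates 2 and 3 (0.920 to 0.963) than with wt replicates 3 and 4 (0.822 to 0.895). Against it, wt replicate 2 was about as low in macrophage genes (-0.93) as the library labelled wt replicate 1 (-1.36). Yet its brighter Card9 probe was well above background (level -3.66, against -5.93 to -4.77 in Card9-/-), though dimly and in 1 library. That level lay below the lowest level well above background on Card9-/- replicates 1 (-3.64) and 4 (-3.47). Detection alone thus does not set wt replicate 2 apart from these. The other Card9 probe was also well above background in wt replicate 2 and on 0 Card9-/- arrays. But its level in wt replicate 2 (-4.57) lay below that in Card9-/- replicate 4 (-3.40), so that level does not set wt replicate 2 apart. A differing share of macrophages in the cells collected, or in the mice's response, was not tested and could bear on the Card9 level itself, which was not above background in the library labelled wt replicate 1.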

How the results depend on the processing

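Slide 1 alone, the slide as a random block, genes on X or Y left out, and wt replicates averaged or set aside were chosen only after the result was seen; the other alternatives were planned. Lower genes numbered 2 (each by over 2-fold) under median scaling, the series matrix, trend and robust moderation, and every probe separately, the last with 11 probes past the threshold, 9 higher. Requiring signal on all 8 arrays left 0 genes in either direction in limma (14427 tested, 1062 at an unadjusted p under 0.05). This filter dropped all 5 called genes by construction, since each was well above background on 0 arrays of 1 genotype. Leaving out X and Y left 0 (1257 unadjusted) by construction, and the slide block 0 (1660 unadjusted). Array weights, which gave wt replicate 2 a weight of 8.85 and wt replicate 3 one of 0.186, called 804 genes, 357 higher and 447 lower (784, 351 and 433 by 2-fold). The replicate block left 3 genes, 3 higher and 0 lower; same-numbered arrays correlated at -0.28 to 0.25 and 1 of 4 wt arrays matched its own number best, so the numbers gave no pairing. Slide 1 alone called 234 (233 higher, 1 lower), setting aside wt replicates 1 and 2 called 745 (233 and 512), and setting aside wt replicates 3 and 4 called 10 (6 and 4). Leaving out 1 library gave 5 to 6 genes, 4 to 5 higher and 1 to 2 lower, and 7 to 21 lists. Lists called numbered 5 in the matrix, 29 without a filter on dim probes, 27 with array weights, 20 with wt replicates 1 and 2 averaged, 28 and 30 with wt replicates 1 and 2 or 3 and 4 set aside, and 0 with an estimated correlation or fry, where the T cell (1.33) and natural killer (2.17) shifts were not called. Without a filter on dim probes the autophagy machinery (-0.11), autophagy receptors, C-type lectin, chemokine, neutrophil, interferon-stimulated, Toll-like receptor, phagocytosis and complement lists were called lower and the B cell, red cell and dendritic lists were not called. The machinery shift ran from -0.19 to 0.013 with 1 library left out. Directions turned as follows. Quantile normalization: autophagy machinery 0.020, autophagy receptors 0.032, C-type lectin list 0.012, interferon-stimulated genes 0.10. Normexp: Tcp10b 0.14, Cdh15 0.014, Rpl37 0.22. Matrix: autophagy receptors 0.011, C-type lectin list 0.12, neutrophils 0.022, interferon-stimulated genes 0.10. Array weights: lysosome 0.22, NF-kB 0.031, endoplasmic reticulum stress 0.057, resident macrophages 1.25, autophagy machinery 0.092, autophagy receptors 0.032, C-type lectin list 0.56, chemokines 0.99, neutrophils 0.54, interferon-stimulated genes 0.48, Toll-like receptors 0.29, phagocytosis 1.07, complement 1.24, Map1lc3b log2 fold change -0.048, Adgre1 1.40, Csf1r 1.27. Of these, array weights called the lysosome, resident macrophage, C-type lectin, chemokine, neutrophil, interferon-stimulated, phagocytosis and complement lists higher, along with cytokines (1.09), and no longer called oxidative phosphorylation (-0.12) or red cells (0.70). Slide block and slide 1 alone: autophagy receptors 0.017 and 0.14, neutrophils 1.12 and 1.07. Averaging wt replicates 1 and 2: cytokines -0.21. With 1 library left out: cytokines -0.30 to 0.80, C-type lectin list -0.47 to 0.22, chemokines -0.98 to 0.38, neutrophils -0.60 to 0.57, interferon-stimulated genes -0.40 to 0.59, phagocytosis -1.32 to 0.22, complement -1.64 to 0.27, Map1lc3b -0.20 to 0.67, Csf1r -2.23 to 0.29. Except where stated, the cause was not tested. Of the other values, 1564 under planned and 274 under added alternatives kept direction and side of the threshold, 70 and 4 lost their call and 51 planned and 3 added ones gained one. T cell shifts ran from 1.00 to 1.49 and natural killer shifts from 1.69 to 2.59. The scan date block amounts to leaving out Card9-/- replicate 3, and list tests were not run with the slide as a random block, which camera does not take. Dim signal limits the Card9 result: its second probe was well above background on 2 wt arrays.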

Other observations

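The test for genes near Card9 was planned, and the genes of this part, apart from the lists they belong to, were chosen after their values were seen.

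Interferon gamma, the main product of activated T and natural killer cells, and the transcription factor Tbx21 that drives it were higher on all 4 Card9-/- arrays than on any wt array, without passing the threshold (Ifng 2.15, SE 0.59, adjusted p = 0.534; Tbx21 1.76, SE 0.54, adjusted p = 0.554; limma). Il12b, a subunit of the cytokines that induce interferon gamma, differed by 3.20 (SE 0.97, adjusted p = 0.553), with levels of 3.15, 0.14, -1.89 and 1.41 in Card9-/- replicates 1 to 4 and -3.85 to -1.69 in wt. Levels of Ifnb1 were 1.94, -0.78, -0.73 and -0.16 in Card9-/- replicates 1 to 4 and -4.34, -3.09, -3.05 and -0.82 in wt replicates 1 to 4.

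Other macrophage genes varied in wt as the resident list did, from the library labelled wt replicate 1 to wt replicate 4: Timd4, a receptor for dying cells, stood at -4.72, -3.68, 4.93 and 2.31, Cd68 at 1.99, 2.16, 6.69 and 5.86, and lysozyme, Lyz2, at 4.55, 4.61, 9.24 and 8.41. The haem synthesis gene Alas2 of red cell precursors stood at 6.89, 4.15, 7.29 and 1.42 in wt and at 8.73, 5.07, 5.92 and 10.2 in Card9-/- replicates 1 to 4. The haemoglobin gene Hbb-bt of the same list was bright on every array, with levels of 6.40 to 9.46 in wt and 7.93 to 10.5 in Card9-/-. It differed little between the genotypes (0.34, SE 0.80, limma adjusted p = 0.959). Red cell RNA was thus high in both groups. The first 2 principal components held 38.0% and 23.8% of the variance, and the first set wt replicates 3 and 4 apart from the other arrays.

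A knockout made in cells of another strain can carry that strain's DNA beside the deleted gene. Of 264 genes tested within 10 Mb of Card9, 15 (5.68%) had an unadjusted p under 0.05, against 1316 of 18246 elsewhere (7.21%; Fisher exact p = 0.401), and 0 passed the adjusted threshold within 5, 10 or 20 Mb, which leaves single genes open. Among these is Lcn4 (chromosome 2, 26523247 to 26523306), whose 4 Card9-/- arrays all lay above the wt arrays (2.69, SE 0.47, adjusted p = 0.277; 2 wt arrays well above background), and whether DNA of another strain underlies it was not tested.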
